A study of Pseudozyma hubeiensis with 12 samples.

How the data were processed

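The deposited table gives, for each locus, a count per library, a signal per library, and for each of 4 comparisons a log2 fold change, a p-value and an adjusted p-value. Per the file headers, the count columns are raw read counts, and every value is a whole number. The signal columns are deposited normalized counts, and each equals the counts divided by 1 size factor per library. Per the file headers, the log2 column is the authors' log2 fold change between 2 groups. The p-value column is the authors' p-value from DESeq2, per the submitters' processing notes. Per the labels, replicates A, B and C are biological replicates, and time points 1 and 2 are exponential growth and nitrogen starvation.

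Upstream steps are known from the submitters' processing notes only. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0.422 and filtered with CASAVA, trimmed with Trim Galore 0.6.1 and cutadapt 2.3, and aligned with HISAT2 2.2.1, and groups were compared in DESeq2. Per the labels, libraries were made with a stranded poly-A kit after quenching in liquid nitrogen and bead milling. The read counter, the strand setting, the genome build and the annotation release are not given in the sources used here. How reads that match more than 1 locus were handled is not given either, so copies named with a suffix such as opt1_2, dal5_3 or fba1_2 may share reads, and their separate levels are uncertain.

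Of 6689 loci, 5877 had deposited normalized counts and 812 had none; of the latter, 781 had no library with 10 reads and 31 had 1. The table names 3358 loci, of which 3 names are repeated, and gives 5258 a product other than a hypothetical protein. All per-sample columns were used (0 left out). Raw counts of the 12 libraries were fitted together in edgeR 4.0.16 (R 4.3.3) with 1 coefficient per group. Genes were kept by filterByExpr (minimum count 10, minimum total 15, CPM of at least 0.395 in 3 libraries), which left 5805, while 269 loci with at least 1 read were not tested. Libraries were scaled by TMM, and genes were tested by quasi-likelihood F tests (glmQLFit, glmQLFTest) with 8 residual degrees of freedom. p values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05.

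The SE of a log2 fold change is approximate, the absolute change divided by the square root of F. Where the lower group had 0 counts, the fold is a bound with 3 counts set for that group, and where it had 1 to 3 counts, a ratio with an exact 95% Poisson interval is printed, which covers counting error only. CPM used TMM-scaled library sizes. Percent of calls, self-test shares and overlap counts describe these genes and are not tests.

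The 5 comparisons, the 29 gene lists and most alternatives were fixed before the data were examined. The lists are search patterns over product and gene names. They cover MEL synthesis, other secondary products, xylose and pentose catabolism, the pentose phosphate pathway, sugar transporters, nitrogen source use, ammonium assimilation, autophagy, the proteasome, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, aminoacyl-tRNA synthetases, translation factors, fatty acid synthesis, triacylglycerol and lipid droplets, beta-oxidation, glycolysis, gluconeogenesis and glyoxylate, the TCA cycle, oxidative phosphorylation, amino acid biosynthesis, chaperones, oxidative stress defence, replication with cell cycle and histones, cell wall, mating and filament genes, plant polysaccharide hydrolases, and storage carbohydrate. Search patterns also caught misfiled genes (leu2 and lys20 in the TCA cycle, leu4 in gluconeogenesis, Rieske-domain PHBOTO_004090 and PHBOTO_000817 in oxidative phosphorylation, cuz1 and rrf1 in the cell cycle), and the list tests were rerun without such genes. The plant polysaccharide hydrolase list is broader than its name and also holds expansins, cutinases and glucan 1,3-beta-glucosidases. Lists were tested with camera in limma 3.58.1 at the preset correlation of 0.01, with Benjamini-Hochberg over the 29 lists of a comparison, and again with the correlation estimated from the data. Counts of members that rose or fell are over all genes tested unless marked as adjusted over the list alone.

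Genes considered for naming in the text were taken by a fixed rule. Per comparison it took the 6 largest rises and 6 largest falls among called, annotated genes with a mean of at least 20 CPM in the higher group and, outside the interaction, no replicate overlap. It added every measured member of focus lists with up to 12 members, and of each other list up to 3 called members with the largest change plus the one with the highest mean CPM. The text names only part of the genes so taken, and the choice among them was not set by the rule. Some genes were chosen after values were seen, namely the exceptions marked so in the text, the members of the locus run in the closing section, and the sulfur, iron and protease genes described there.

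The deposited DESeq2 table had 4787, 4762, 1414 and 2654 of 5877 genes at an adjusted p under 0.05 for starvation on glucose, starvation on xylose, xylose in exponential growth and xylose in starvation. Its log2 fold changes correlated with those used here at Pearson 1.00, 1.00, 1.00 and 0.997 across genes. Of 4696, 4711, 1192 and 2386 genes called in both, 0 had opposite signs.

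A self-test drew negative binomial counts with the mean levels, library sizes and dispersions estimated from the data, planted changes of 1.5-, 2- and 4-fold in 67, 67 and 66 genes per comparison, and ran the same code. Shares recovered are printed with each comparison. Among calls on these simulated counts 3.76, 4.61, 3.30, 4.31 and 6.08% were false for the 5 comparisons in the order of the text. Camera called 0 of 20 random lists in each comparison, and fry called 2, 0, 0, 1 and 3. Simulated genes were drawn independently, so these lists do not test camera on genes that vary together, as real list members may. Each gene also had 1 dispersion for all groups, so the shares leave out the wider spread of weak genes in starved glucose.

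Alternatives were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and library-size scaling, no filter and a stricter filter, stricter thresholds, fits of only the compared groups, block terms, leaving out each library, and fry. Lists without misfiled genes, sample quality weights, counts divided by the low-count variance-to-mean ratio, and a mean count filter of 500 were added after the data were seen. A pseudocount alternative was not run because raw counts exist.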

Results

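RNA was sequenced from Pseudozyma hubeiensis strain BOT-O, a basidiomycete yeast that secretes mannosylerythritol lipids (MEL), which are glycolipid surfactants. Cultures grew on glucose or on xylose in yeast nitrogen base medium that held, at the start, 80 times as much carbon as nitrogen by weight. They were sampled in exponential growth (time point 1) and in nitrogen starvation (time point 2). Phase and time point coincide in all libraries. Changes called starvation changes below therefore cannot be told apart from those of culture age or other differences between the time points. The 4 combinations of sugar and phase gave 4 groups of 3 biological replicates (A, B and C), or 12 libraries of poly-A selected RNA. Total counts for replicates A, B and C, in units of 1e6, were 28.4, 32.4 and 19.4 in exponential glucose, 30.5, 29.7 and 28.6 in exponential xylose, 15.1, 16.9 and 16.7 in starved glucose, and 18.6, 23.4 and 27.3 in starved xylose. Of 6689 loci in the table, 5805 had enough counts to be tested and 615 stood at 0 in all 12 libraries. Levels are given in CPM (counts scaled to a library total of 1e6) as mean ± SD, n = 3 libraries per group, and changes as log2 fold changes ± SE.

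Growth phase separated the libraries more than sugar did. The first principal component held 82.8% of the variance and placed the exponential libraries at -69.5 to -61.0 and the starved libraries at 58.8 to 73.8. The second held 7.54% and separated glucose from xylose libraries in both phases, with more distance between the starved groups. Spearman correlation across the tested genes was 0.979 to 0.997 between replicates of a group, 0.922 to 0.967 between sugars in the same phase, and 0.582 to 0.680 between phases. The 10 highest loci took 5.72 to 6.80% of the counts in exponential libraries and 10.3 to 12.0% in starved libraries. Replicates of every group differed by more than counting error, with chi-square per degree of freedom of 11.5 to 97.0, so no library was a second copy of another.

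**Figure D1:**
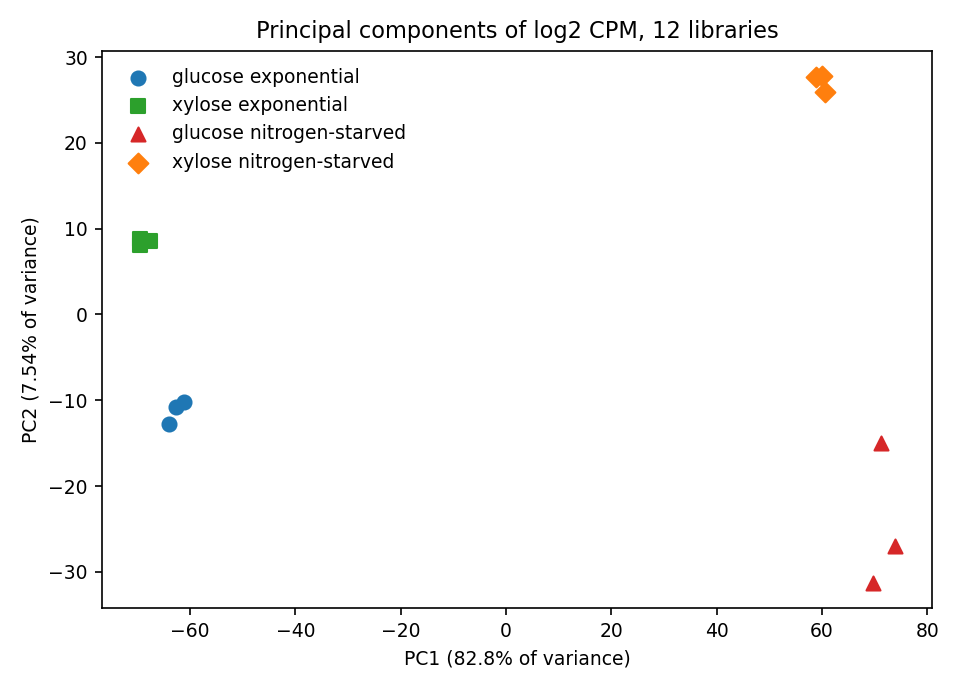
Each point is 1 of the 12 libraries on the first 2 principal components of log2 CPM. Colour and shape mark the group.

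Weakly expressed genes were measured less evenly in starved glucose than in the other groups. At mean counts of 10 to 100, the variance between replicates was a median of 12.4 times the mean in starved glucose, 2.82 times in starved xylose, 1.27 times in exponential glucose and 1.22 times in exponential xylose. Above a mean count of 3000 the coefficient of variation was 8.69, 7.86, 4.36 and 4.99% in the same order. Between 21 and 39 loci stood at 0 in a starved-glucose library although the other 2 libraries of the group averaged 10 counts or more, against 0 to 4 in any library of the other groups. Changes of weak genes in starved glucose are therefore the least precise of this report.

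**Figure D2:**
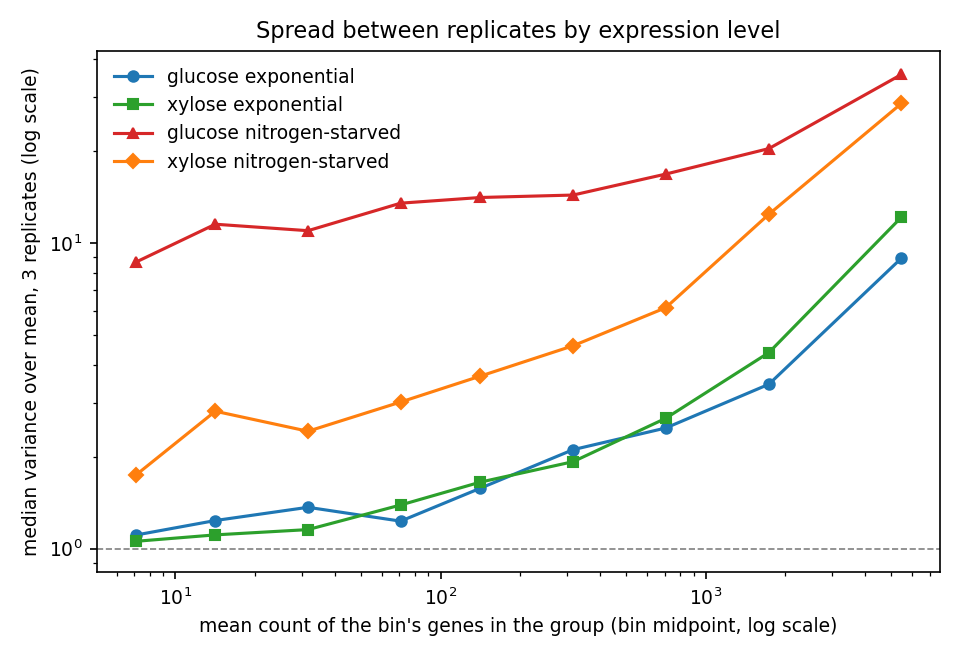
The median ratio of variance to mean between the 3 replicates of each group is drawn against mean count, with genes binned by mean count. Counting error alone would give 1, and genes with a mean of 10000 counts or more are left out.

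In nitrogen-starved glucose cultures the MEL genes rose and the genes of protein synthesis fell. The MEL acyltransferase mac1 (PHBOTO_003090), which loads a fatty acyl chain onto the sugar head group, rose by 9.15 ± 0.18, from 1.05 ± 0.0976 to 594 ± 114 CPM (567-fold). The mannosyltransferase emt1 (PHBOTO_003091), which makes the head group, rose by 8.58 ± 0.19 to 143 ± 15.9 CPM (382-fold). The exporter mmf1 (PHBOTO_003089) rose by 7.24 ± 0.18 to 148 ± 3.57 CPM, the second acyltransferase mac2 (PHBOTO_003092) by 4.90 ± 0.14 to 137 ± 15.7 CPM, and the acetyltransferase mat1 (PHBOTO_003088) by 2.26 ± 0.12 to 110 ± 18.9 CPM. The sixth gene of the MEL list, mmf1_(YIL051C), is a mitochondrial protein that the name search caught, and it fell by 1.98 ± 0.09. The MEL list had a median of 6.07 and a camera adjusted p of 1.58e-05 (adjusted p = 0.0526 with an estimated correlation).

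**Figure D3:**
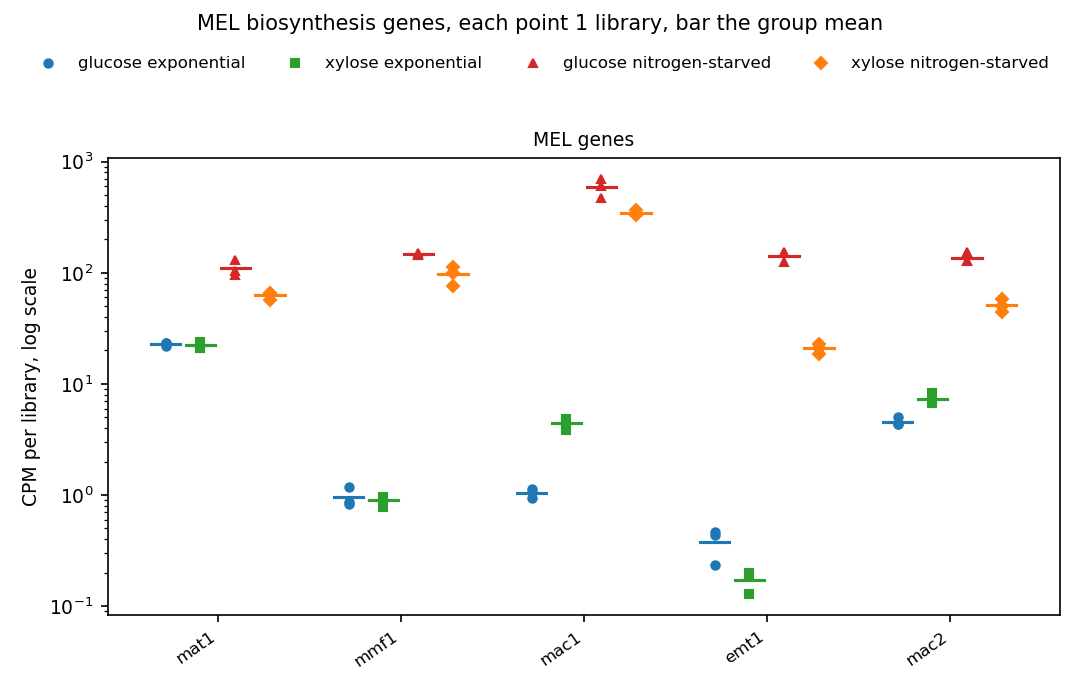
CPM of the 5 MEL genes in each of the 12 libraries, on a log scale, with bars at group means. Colour and shape mark the group.

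The largest rises on glucose included a glycosyltransferase, P450 enzymes and transporters of nitrogen compounds. The glycosyltransferase PHBOTO_006524 had 2 counts in all exponential glucose libraries together and 3645 ± 589 CPM in starvation, a ratio of 154194 with a counting interval of 42685 to 1273226. The cytochrome P450 erg11_3 (PHBOTO_006520), annotated as a lanosterol demethylase, had 1 count and then 1978 ± 410 CPM, a ratio of 167386 with a counting interval of 30042.5 to 6611406. The P450 PHBOTO_006516 rose by 15.80 ± 0.24 to 3665 ± 320 CPM, the reductase gre2_2 by 13.68 ± 0.26 to 1469 ± 257 CPM, and the fatty acid synthase subunit fas2 by 9.45 ± 0.13 to 9555 ± 428 CPM. Genes whose names end in _2, _3 and so on are copies that may share reads. The oligopeptide transporter opt1_2 rose by 12.85 ± 0.28 to 1698 ± 75.6 CPM. The allantoate permease dal5_3 rose by 10.40 ± 0.20 to 1396 ± 120 CPM, the purine permease PHBOTO_003947 by 9.39 ± 0.18 to 11529 ± 1384 CPM, and the urate oxidase PHBOTO_000156, which opens the purine ring for nitrogen release, by 6.94 ± 0.16 to 15337 ± 2474 CPM.

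Lists for nitrogen release rose on glucose as well. Of 66 genes for uptake and use of nitrogen sources, 49 rose and 10 fell, with a median of 1.08 and a camera adjusted p of 1.20e-09 (adjusted p = 0.0202 with an estimated correlation). Autophagy and vacuolar protease genes (30) rose in 23 cases and fell in 4, with a median of 1.15 and a camera adjusted p of 1.08e-04 (adjusted p = 0.0526 with an estimated correlation). Among them the vacuolar carboxypeptidase ybr139w_4 rose by 6.38 ± 0.14, the autophagosome protein atg8 by 2.57 ± 0.15 and the vacuolar protease pep4 by 1.59 ± 0.09. A second locus annotated as autophagy-related protein 8, PHBOTO_005562, fell by 0.63 ± 0.09 (picked out after its value was seen). Glutamine synthetase gln1, which fixes ammonium, rose by 0.91 ± 0.08 to 4771 ± 179 CPM, the glutamate dehydrogenase gdh2 rose by 0.67 ± 0.12, and the glutamate synthase glt1 fell by 0.58 ± 0.09. Another glutamate synthase locus, PHBOTO_003851 (mean level 5.73 CPM), rose by 1.71 ± 0.31. The 5-gene ammonium list, which also holds the folate enzyme met7 (a fall of 2.86 ± 0.19), was not called by camera (adjusted p = 0.951). Its median was 0.67, its mean -0.03 and its test pointed down.

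Genes that make proteins fell together on glucose. Of 79 cytosolic ribosomal proteins, 76 fell and only the ubiquitin fusion rpl40a rose (by 1.01 ± 0.08, picked out after its value was seen). The median was -3.29 and the camera adjusted p 2.39e-37 (adjusted p = 0.120 with an estimated correlation). The small-subunit protein rps0b fell by 4.50 ± 0.12, from 1811 ± 24.2 to 80.2 ± 8.17 CPM. Translation factors fell in 34 of 42 cases (median -1.63, camera adjusted p = 2.60e-08, and adjusted p = 0.120 with an estimated correlation), among them the elongation factor tef1 (-2.23 ± 0.09) and the initiation factor sui2 (-2.92 ± 0.10). Mitochondrial ribosomal proteins fell in 44 of 46 cases (median -1.58, camera adjusted p = 1.76e-09, and adjusted p = 0.366 with an estimated correlation). Ribosome biogenesis genes fell in 78 of 91 cases (median -1.38, camera adjusted p = 2.38e-08, and adjusted p = 0.558 with an estimated correlation), among them the snoRNP protein nop58 (-2.79 ± 0.15). Aminoacyl-tRNA synthetases fell in 15 of 17 cases (median -1.38, camera adjusted p = 5.78e-04, and adjusted p = 0.120 with an estimated correlation), but the second aspartate enzyme dps1_2 rose by 3.41 ± 0.15.

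Amino acid biosynthesis genes fell on glucose as well, and single transporters fell further. Amino acid biosynthesis fell in 44 of 53 genes (median -1.52, camera adjusted p = 3.54e-09, and adjusted p = 0.0202 with an estimated correlation). The S-adenosylmethionine synthase sam2 fell by 5.06 ± 0.11, from 1657 ± 34.7 to 49.8 ± 6.33 CPM (33.3-fold), and the branched-chain enzyme ilv5 fell by 3.56 ± 0.10. The sulfhydrylase met17, which builds sulfide into amino acids, fell by 8.32 ± 0.28 and the acidic amino acid permease dip5_3 fell by 8.42 ± 0.49, from 1156 ± 44.6 to 3.39 ± 3.12 CPM. The sugar transporter PHBOTO_004493 went from 69.6 ± 8.75 CPM to 0 in all 3 starved libraries, at least 1116-fold lower if the starved group is set at 3 counts. The ferric reductase fre2 fell by 6.36 ± 0.41 and the maltose permease mal31 fell by 6.35 ± 0.31.

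Beta-oxidation and lipid droplet genes rose on glucose, and proteasome genes fell. Beta-oxidation and peroxisome genes rose in 36 of 51 cases and fell in 4 (median 0.71, camera adjusted p = 0.00370, and adjusted p = 0.120 with an estimated correlation), with the peroxisomal carrier ant1_2 up by 4.31 ± 0.11 and the multifunctional enzyme fox2 up by 2.38 ± 0.10. Triacylglycerol and lipid droplet genes rose in 8 of 13 cases (median 0.90, camera adjusted p = 0.0433, and adjusted p = 0.120 with an estimated correlation), with the droplet phospholipase lpl1 up by 4.73 ± 0.11, the droplet coat protein PHBOTO_004628 up by 2.42 ± 0.12 and the diacylglycerol acyltransferase dga1 up by 1.54 ± 0.11. That camera call ended without starved glucose B (adjusted p = 0.0527) or C (adjusted p = 0.0589). Proteasome genes fell in 31 of 43 cases (median -0.62, camera adjusted p = 0.0452, and adjusted p = 0.684 with an estimated correlation), while their regulator rpn4 rose by 2.74 ± 0.11. Camera lost the proteasome call without exponential glucose B (adjusted p = 0.0507) or C (adjusted p = 0.0520) and without starved glucose B (adjusted p = 0.0553) or C (adjusted p = 0.0754). The stress protein hsp12 rose by 4.69 ± 0.16 and the peroxidase ccp1_2 by 3.77 ± 0.12, and the peroxiredoxin prx1 fell by 4.06 ± 0.13.

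Central carbon genes moved in both directions on glucose. The gluconeogenic enzymes fbp1 and pck1 rose by 2.78 ± 0.17 and 1.30 ± 0.20, the glyoxylate enzyme icl1 by 0.90 ± 0.11, and the transaldolase nqm1 by 2.11 ± 0.11 to 5612 ± 764 CPM. The xylose reductase xr1 fell by 2.44 ± 0.13 and the xylitol dehydrogenase xyl2 fell by 1.62 ± 0.09. TCA cycle genes fell in 11 of 17 cases (median -0.74, camera adjusted p = 0.0483, and adjusted p = 0.684 with an estimated correlation), among them the isocitrate dehydrogenase idp1 (-1.93 ± 0.10) and the aconitase aco1 (-1.01 ± 0.09). That list also caught the leucine and lysine enzymes leu2 and lys20, and camera did not call it without the misfiled genes (adjusted p = 0.324). Camera also lost this call without exponential xylose C (adjusted p = 0.0504), starved glucose A (adjusted p = 0.0961), starved glucose B (adjusted p = 0.0553), starved xylose A (adjusted p = 0.0704), starved xylose B (adjusted p = 0.0580) or starved xylose C (adjusted p = 0.0534).

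Other lists were not called by camera on glucose. Xylose and pentose catabolism (8 genes, adjusted p = 0.759), the pentose phosphate pathway (11 genes, median 0.43, adjusted p = 0.420), glycolysis (19 genes, adjusted p = 0.457), gluconeogenesis and glyoxylate (8 genes, adjusted p = 0.893) and storage carbohydrate (12 genes, median 0.89, adjusted p = 0.125) stayed uncalled. The same held in camera for fatty acid synthesis (10 genes, adjusted p = 0.436), oxidative phosphorylation (44 genes, median -0.46, adjusted p = 0.125, but 0.0229 without misfiled genes), chaperones (21 genes, adjusted p = 0.951) and oxidative stress defence (31 genes, adjusted p = 0.242). Replication, cell cycle and histone genes (105, adjusted p = 0.115), cell wall genes (48, adjusted p = 0.242) and plant polysaccharide hydrolases (43, adjusted p = 0.878) were uncalled in camera too. Signs differed in 3 uncalled lists: other secondary products (median 0.28, mean -0.04, test down, camera adjusted p = 0.754), sugar transporters (median 0.84, mean -0.48, test up, camera adjusted p = 0.436) and mating genes (median -0.07, mean -0.01, test up, camera adjusted p = 0.893).

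On glucose 4714 of 5805 genes changed by edgeR quasi-likelihood (Benjamini-Hochberg), 2327 up and 2387 down, and 2587 of them by 2-fold or more. Replicates of the 2 groups did not overlap for 4729 genes, or 81.5% of all genes tested, where 10% would be expected by chance. In the self-test 82.1, 89.6 and 100% of planted changes of 1.5-, 2- and 4-fold were recovered here.

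In nitrogen-starved xylose cultures the same 5 MEL genes rose and most genes of protein synthesis fell. Here emt1 rose by 6.90 ± 0.22, from 0.171 ± 0.0369 to 21.0 ± 2.2 CPM, and mmf1 by 6.75 ± 0.18, from 0.895 ± 0.0949 to 96.7 ± 18.3 CPM. The acyltransferases mac1 and mac2 rose by 6.28 ± 0.15 (4.41 ± 0.498 to 343 ± 19.3 CPM) and 2.80 ± 0.13 (7.29 ± 0.851 to 51.0 ± 6.80 CPM), and the acetyltransferase mat1 by 1.49 ± 0.12. The MEL list had a median of 4.54 and a camera adjusted p of 0.00110 (adjusted p = 0.131 with an estimated correlation).

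The oligopeptide transporter opt1_2 had the largest rise on xylose, 13.45 ± 0.29, from 0.130 ± 0.174 to 1497 ± 85.3 CPM. The P450 PHBOTO_002762 rose by 12.18 ± 0.41 to 2353 ± 715 CPM and the sulfonate dioxygenase-like PHBOTO_005702 by 10.81 ± 0.31 to 15184 ± 2015 CPM. For the glycosyltransferase PHBOTO_006524, 2 counts in exponential xylose against 40.3 ± 5.54 CPM in starvation gave a ratio of 1886 with a counting interval of 522 to 15571. The amino acid transporter PHBOTO_003010 rose by 10.10 ± 0.23, dal5_3 by 9.51 ± 0.19 and the urate oxidase PHBOTO_000156 by 7.80 ± 0.17 to 16644 ± 1461 CPM. Nitrogen source genes rose in 46 of 66 cases and fell in 14 (median 1.09, camera adjusted p = 9.12e-09, and adjusted p = 0.0376 with an estimated correlation). Autophagy genes rose in 20 of 30 cases (median 0.76, camera adjusted p = 0.00475, and adjusted p = 0.131 with an estimated correlation), with the membrane protein atg9 up by 2.36 ± 0.08.

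The urea transporter dur3_2 had the deepest fall on xylose, -10.10 ± 0.36, from 523 ± 126 to 0.434 ± 0.325 CPM. The sulfonate dioxygenase-like PHBOTO_005008 changed by -9.97 ± 0.28, met17 by -7.48 ± 0.26, dip5_3 by -7.46 ± 0.45 and the sulfate permease sul1 by -7.15 ± 0.17, from 1972 ± 402 to 13.9 ± 1.62 CPM. Cytosolic ribosomal proteins fell in 77 of 79 cases (median -2.48, camera adjusted p = 2.35e-28, and adjusted p = 0.183 with an estimated correlation), with rps0b at -3.76 ± 0.12, while rpl40a rose by 0.89 ± 0.08. Mitochondrial ribosomal proteins fell in 42 of 46 cases (median -1.21, camera adjusted p = 4.55e-06, and adjusted p = 0.563 with an estimated correlation), and adjusted over the list alone 1 of them rose and 42 fell. Falls also covered 68 of 91 ribosome biogenesis genes (median -0.86, camera adjusted p = 1.31e-04, and adjusted p = 0.702 with an estimated correlation), 31 of 42 translation factors (median -1.57, camera adjusted p = 5.36e-08, and adjusted p = 0.134 with an estimated correlation) and 16 of 17 aminoacyl-tRNA synthetases (median -1.54, camera adjusted p = 4.09e-04, and adjusted p = 0.131 with an estimated correlation). Amino acid biosynthesis fell in 40 of 53 genes (median -1.18, camera adjusted p = 1.46e-07, and adjusted p = 0.0376 with an estimated correlation), with sam2 at -4.93 ± 0.11. Proteasome genes fell in 33 of 43 cases (median -0.79, camera adjusted p = 0.00408, and adjusted p = 0.563 with an estimated correlation).

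Beta-oxidation genes rose on xylose, and fatty acid synthesis genes moved in both directions. Beta-oxidation genes rose in 37 of 51 cases (median 0.63, camera adjusted p = 0.00137, and adjusted p = 0.131 with an estimated correlation), ant1_2 by 5.69 ± 0.12 and fox2 by 2.65 ± 0.10. Triacylglycerol genes rose in 9 of 13 cases and fell in 3 (sct1, ypr147c and slc1, named after their values were seen), without a camera call (median 0.84, adjusted p = 0.0642). The gluconeogenic fbp1 and pck1 rose by 4.36 ± 0.18 and 4.35 ± 0.22 and the glyoxylate enzymes icl1 and mls1 by 1.65 ± 0.11 and 0.94 ± 0.11. The mitochondrial malic enzyme mae1, which turns malate into pyruvate, rose by 3.44 ± 0.22 and fas2 by 3.41 ± 0.10. Of the 10 fatty acid genes these and ole1 and PHBOTO_001745 rose, and acc1, acl1, fas1, elo2 and PHBOTO_001248 fell (some named after their values were seen). The alternative oxidase PHBOTO_002482, which bypasses part of the respiratory chain, rose by 5.51 ± 0.21 from 104 ± 9.65 to 4765 ± 405 CPM. The disaggregase hsp104 rose by 7.11 ± 0.58 to 2952 ± 1644 CPM and the chaperone ssa4 by 4.09 ± 0.35 to 8601 ± 2985 CPM. The chaperone list, with 12 rises and 4 falls among 21 genes, was not called by camera (median 0.71, adjusted p = 0.355). The beta-xylanase PHBOTO_003675 rose by 6.04 ± 0.19 to 365 ± 30.6 CPM, the xylulose kinase xks1 fell by 2.37 ± 0.16 and the transaldolase PHBOTO_006510 fell by 3.58 ± 0.17. Signs differed in 4 lists that camera left uncalled: other secondary products (median -0.09, mean 0.34, test down), ammonium assimilation (median 0.18, mean -0.09, test up), fatty acid synthesis (median -0.22, mean 0.48, test down) and cell wall (median -0.20, mean 0.17, test down).

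On xylose 4717 genes changed by edgeR quasi-likelihood, 2358 up and 2359 down, and 2539 by 2-fold or more. Without replicate overlap were 4932 genes (chance 10%), and 4670 were also called. The self-test recovered 79.1, 94.0 and 98.5% of planted changes of 1.5-, 2- and 4-fold in this comparison.

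From exponential growth to nitrogen starvation 3996 genes changed in the same direction on both sugars, 1986 up and 2010 down. Independent calls would have given 945 and 970. The 2 responses correlated across genes (Pearson 0.881, Spearman 0.887), and the 2 comparisons share no libraries. The MEL genes mac1, emt1, mmf1, mac2 and mat1 are in the shared rises, as are opt1_2, dal5_3, gln1 and ant1_2, and the shared falls include rps0b, tef1, sam2, met17 and dip5_3. At 2-fold or more in both, 1066 genes rose and 956 fell. Opposite calls were made for 147 genes, 68 rising on glucose and falling on xylose and 79 the reverse, and 571 were called on glucose only and 574 on xylose only. Among the genes with opposite calls was the transaldolase PHBOTO_006510, with 1.74 ± 0.17 on glucose and -3.58 ± 0.17 on xylose.

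**Figure D4:**
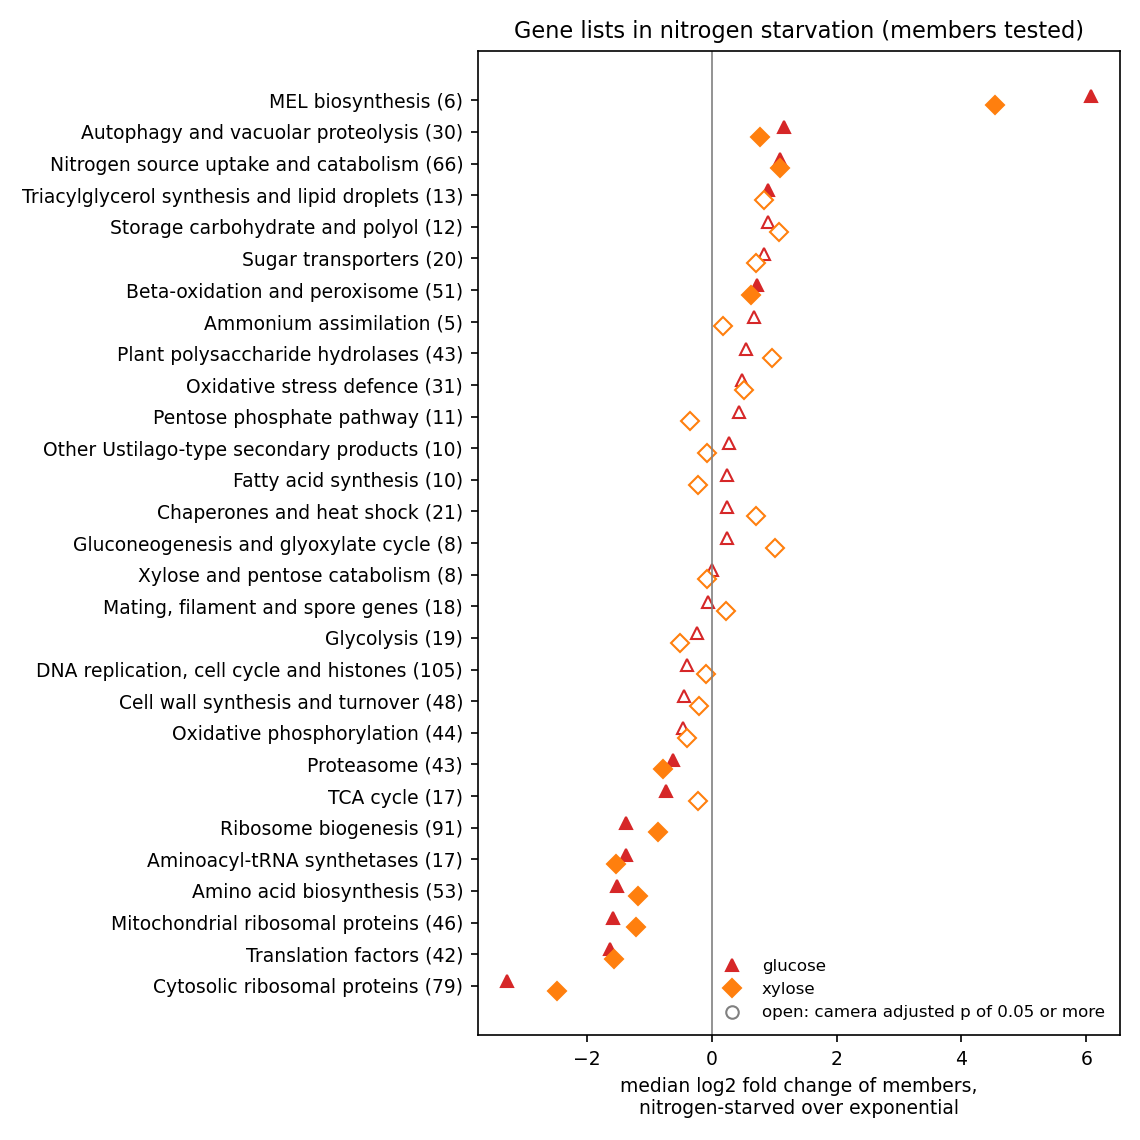
Median log2 fold change of the 29 gene lists in nitrogen starvation on glucose and on xylose, with the number of members tested. Open markers have a camera adjusted p of 0.05 or more.

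In exponential growth, cells on xylose carried more transcript for xylose catabolism and less for gluconeogenesis than cells on glucose. The xylulose kinase xks1, the last step before the pentose phosphate pathway, was higher by 4.52 ± 0.17 (27.7 ± 0.974 against 633 ± 19.6 CPM, 22.9-fold). The xylitol dehydrogenase xyl2 was higher by 2.49 ± 0.09 (304 ± 11.1 against 1709 ± 33.9 CPM), and the xylose reductase xr3 by 0.53 ± 0.12. The reductase with the highest level, xr1, read 753 ± 83.0 and 961 ± 46.2 CPM without a call by edgeR quasi-likelihood (log2 0.35 ± 0.13, adjusted p = 0.0614). Of 8 xylose and pentose genes 4 rose and 0 fell, and 5 and 0 adjusted over the list alone (median 0.44, camera adjusted p = 5.22e-08, and adjusted p = 0.0168 with an estimated correlation).

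**Figure D5:**
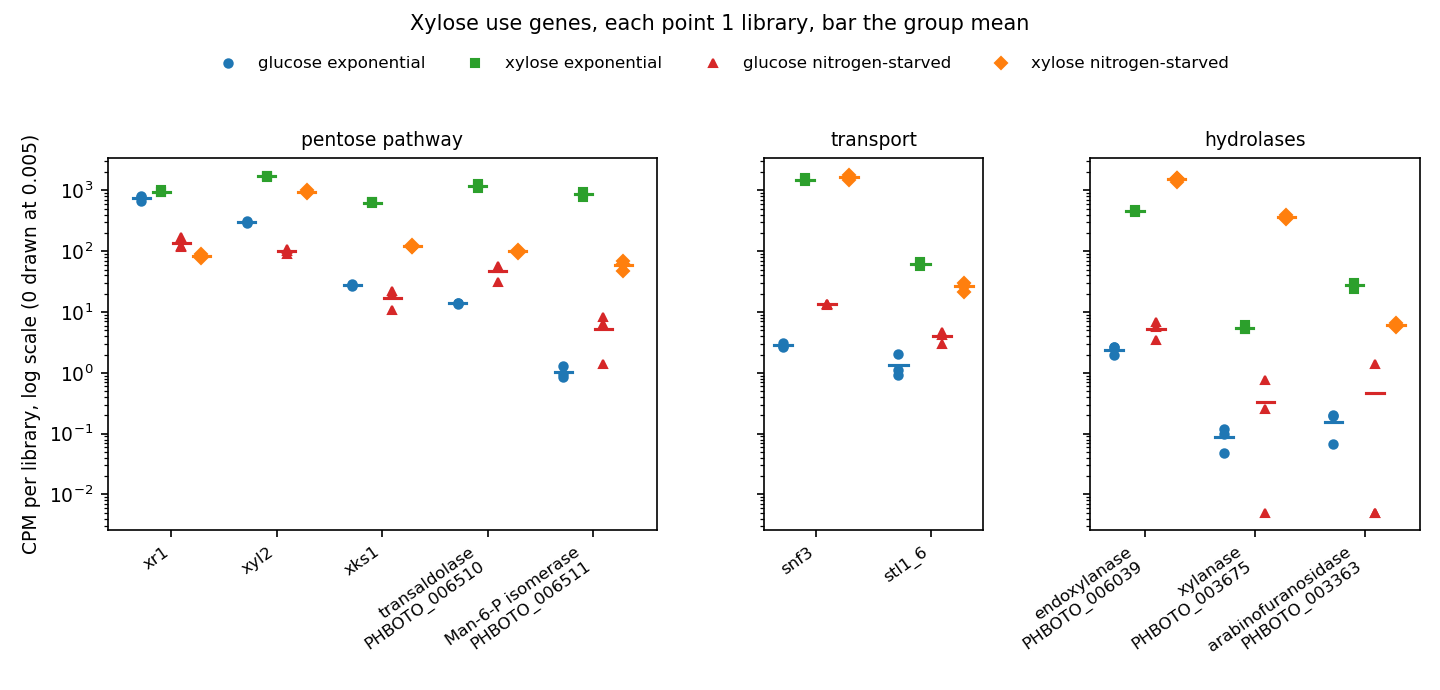
CPM of xylose catabolism, transport and hydrolase genes in each of the 12 libraries, on a log scale with 0 drawn at the bottom, and bars at group means. Colour and shape mark the group.

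Sugar handling changed beyond these enzymes. The mannose-6-phosphate isomerase PHBOTO_006511 was higher on xylose by 9.75 ± 0.39 (1.05 ± 0.235 against 882 ± 83.7 CPM), the transaldolase PHBOTO_006510, next in locus number, by 6.42 ± 0.19 (13.9 ± 0.387 against 1196 ± 89.6 CPM), and the low-glucose sensor snf3 by 9.07 ± 0.13 (2.83 ± 0.219 against 1514 ± 88.9 CPM). The sugar transporters stl1_6 and PHBOTO_001594 were higher by 5.59 ± 0.24 and 4.18 ± 0.09, and the drug antiporter yhk8_5 was lower by 7.85 ± 0.17 (254 ± 6.64 against 1.10 ± 0.272 CPM). Of 20 sugar transporters 8 rose and 3 fell, and adjusted over the list alone 10 rose and 3 fell (median 0.21, camera adjusted p = 0.00204, and adjusted p = 0.244 with an estimated correlation). In the pentose phosphate pathway the oxidative enzymes zwf1 and gnd2 were higher by 0.72 ± 0.08 and 0.69 ± 0.09, and the transketolase tkl1 by 0.62 ± 0.09. Of 11 genes 5 rose and 0 fell, and 6 rose adjusted over the list alone (median 0.62, camera adjusted p = 3.46e-07, and adjusted p = 0.0547 with an estimated correlation). Plant polysaccharide hydrolases rose in 17 of 43 cases and fell in 2, and in 18 and 4 adjusted over the list alone (median 0.23, camera adjusted p = 1.56e-08, and adjusted p = 0.0168 with an estimated correlation), with the xylanase PHBOTO_006039 up by 7.54 ± 0.19 and the arabinofuranosidase PHBOTO_003363 by 7.44 ± 0.59.

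Genes of gluconeogenesis, the malic enzyme and some nitrogen permeases moved too. On xylose the gluconeogenic pck1 differed by -2.00 ± 0.20 (519 ± 69.3 against 130 ± 21.4 CPM) and fbp1 by -0.98 ± 0.16, and the glyoxylate enzyme icl1 by -1.40 ± 0.11. Of 8 genes 6 fell and 0 rose (median -0.78, camera adjusted p = 1.84e-04, and adjusted p = 0.145 with an estimated correlation). The malic enzyme mae1 was lower by 2.12 ± 0.21 and the alternative oxidase PHBOTO_002482 was lower by 3.11 ± 0.19. The urea transporter dur3_2 was higher by 7.94 ± 0.30 (2.25 ± 1.06 against 523 ± 126 CPM) and the sorbitol dehydrogenase sor1 by 3.80 ± 0.12. Of the MEL genes mac1 was higher by 2.08 ± 0.20, at 4.41 ± 0.498 CPM, and mac2 by 0.67 ± 0.14. Ribosomal protein genes were not called singly (0 of 79; camera adjusted p = 0.381 for the list), although 14 of 46 mitochondrial ribosomal proteins fell and 27 fell adjusted over the list alone (median -0.29, camera adjusted p = 7.48e-04, and adjusted p = 0.630 with an estimated correlation).

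Other called lists had small medians. Ribosome biogenesis fell in 11 of 91 genes, or 8 adjusted over the list alone (median -0.21, camera adjusted p = 0.00642, and adjusted p = 0.746 with an estimated correlation), and beta-oxidation in 11 of 51, or 12 adjusted over the list alone (median -0.13, camera adjusted p = 0.0155, and adjusted p = 0.244 with an estimated correlation). Storage carbohydrate genes rose in 4 and fell in 3 of 12 cases, and in 4 and 4 adjusted over the list alone (median 0.07, camera adjusted p = 0.0183, and adjusted p = 0.141 with an estimated correlation). Glycolysis rose in 6 and fell in 2 of 19 cases (fba1 and glk1, named after their values were seen), and in 7 and 2 adjusted over the list alone (median 0.22, camera adjusted p = 0.0495, and adjusted p = 0.447 with an estimated correlation), with the aldolase fba1_2 up by 1.38 ± 0.10 and the isomerase pgi1 by 1.12 ± 0.11. Camera lost the glycolysis call without exponential glucose A (adjusted p = 0.0535) or C (adjusted p = 0.0738), exponential xylose A (adjusted p = 0.0588) or B (adjusted p = 0.0799), starved glucose C (adjusted p = 0.0539) or starved xylose C (adjusted p = 0.0516). Signs differed in fatty acid synthesis (median 0.18, mean -0.12, test up) and oxidative stress defence (median -0.01, mean -0.04, test up), which camera left uncalled.

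Between the sugars in exponential growth 1203 genes differed by edgeR quasi-likelihood, 577 higher and 626 lower on xylose, and 247 of them by 2-fold or more. That count was 791 without exponential glucose B, 2458 in a fit of the exponential libraries alone, 1937 with counts divided by the low-count variance-to-mean ratio and 2597 in limma-voom with quality weights per group. Replicates did not overlap for 3090 genes (chance 10%), and 1199 of these were called. Planted changes of 1.5-, 2- and 4-fold were recovered in 83.6, 92.5 and 93.9% of cases.

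In starved cells on xylose, several enzymes that break down plant polysaccharides were higher than on glucose, and MEL genes were lower. The beta-xylanase PHBOTO_003675 was higher by 10.07 ± 0.27 (0.337 ± 0.384 against 365 ± 30.6 CPM), the xylanase PHBOTO_006039 by 8.17 ± 0.19 (5.34 ± 1.74 against 1538 ± 142 CPM), the arabinofuranosidase PHBOTO_004942 by 6.51 ± 0.17 and the polygalacturonase pgu1 by 5.63 ± 0.17 to 500 ± 28.6 CPM. Of the 43 genes in the plant polysaccharide hydrolase list 21 rose and 4 fell, and 21 and 6 adjusted over the list alone (median 0.30, camera adjusted p = 3.34e-14, and adjusted p = 0.00617 with an estimated correlation). These rises also cover expansins, cutinases and glucan 1,3-beta-glucosidases. Examples picked out after their values were seen are the expansin PHBOTO_001076 (2.15 ± 0.20) and the cutinase PHBOTO_005903 (4.97 ± 0.28). Among the MEL genes emt1 differed by -2.76 ± 0.13 (143 ± 15.9 against 21.0 ± 2.2 CPM), mac2 by -1.42 ± 0.12, mat1 by -0.80 ± 0.11, mac1 by -0.79 ± 0.12 and mmf1 by -0.62 ± 0.12. The MEL list had a median of -0.80 and a camera adjusted p of 1.12e-04 (adjusted p = 0.0640 with an estimated correlation).

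The glycosyltransferase PHBOTO_006524 and loci with numbers close to it differed more. That glycosyltransferase differed on xylose by -6.50 ± 0.16 (3645 ± 589 against 40.3 ± 5.54 CPM), the P450s erg11_3 and PHBOTO_006516 by -6.52 ± 0.18 and -5.94 ± 0.14, the reductase gre2_2 by -6.21 ± 0.17, the acetyltransferase PHBOTO_006519 by -6.11 ± 0.15 and the fatty acid synthase subunit fas2 by -5.46 ± 0.11 (9555 ± 428 against 217 ± 16.0 CPM). The acetyl-CoA carboxylase acc1, which supplies fatty acid synthesis, was lower (1209 ± 16.8 against 427 ± 20.8 CPM) and the malic enzyme mae1 was higher by 1.24 ± 0.20. Fatty acid synthesis rose in 3 and fell in 4 of 10 genes (median -0.32, camera adjusted p = 5.21e-04, and adjusted p = 0.134 with an estimated correlation). The difference of fas2 was the largest in this list, and no list test without it is given here. Of the sugar genes snf3 was higher by 6.94 ± 0.12 (13.4 ± 0.122 against 1640 ± 153 CPM), xyl2 by 3.26 ± 0.10, xks1 by 2.81 ± 0.17 and the galactose transporter gal2 by 3.75 ± 0.21, and xr1 was lower by 0.72 ± 0.13. Xylose and pentose genes had a median of -0.03, a mean of 0.63 and a test that pointed up (2 rose, 1 fell; camera adjusted p = 0.0115, and adjusted p = 0.209 with an estimated correlation). Sugar transporters rose in 9 and fell in 2 of 20 cases (median 0.59, or 0.43 with genes at 0 set to their bounds; camera adjusted p = 1.39e-04, and adjusted p = 0.170 with an estimated correlation).

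Ribosomal protein, cell wall and chaperone genes were higher in starved xylose. Of 79 cytosolic ribosomal proteins 71 were higher and 0 lower, and 73 adjusted over the list alone (median 0.64, camera adjusted p = 9.52e-12, and adjusted p = 0.476 with an estimated correlation), with rpl25 higher by 1.14 ± 0.14 (158 ± 20.9 against 349 ± 83.7 CPM). Cell wall genes rose in 22 and fell in 3 of 48 cases (kre2, PHBOTO_003185 and PHBOTO_006067, named after their values were seen), and in 22 and 4 adjusted over the list alone (median 0.21, camera adjusted p = 0.00214, and adjusted p = 0.0640 with an estimated correlation). The chitin deacetylase cda2_5 was higher by 3.53 ± 0.30. Proteasome genes fell in 25 of 43 cases (median -0.28, camera adjusted p = 8.99e-04, and adjusted p = 0.476 with an estimated correlation), with the subunit pre7 at -0.70 ± 0.09. The disaggregase hsp104 was higher by 2.93 ± 0.47, ssa4 by 1.93 ± 0.32 and the co-chaperone sti1 by 1.46 ± 0.22, and the histone genes htb2 and hhf1 by 1.39 ± 0.09 and 1.35 ± 0.08. Threonine synthase thr4 and the aminotransferase bat1 were higher by 1.51 ± 0.12 and 1.15 ± 0.12.

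Several of the smaller list calls were lost when any of certain libraries was left out. These libraries are named here with the camera adjusted p found without them. Chaperones rose in 12 of 21 cases (median 0.73, camera adjusted p = 0.0419, and adjusted p = 0.476 with an estimated correlation), a call that ended without starved glucose A (0.0839) or B (0.0851) or starved xylose B (0.0672) or C (0.0556). Ribosome biogenesis rose in 35 and fell in 3 of 91 cases, or in 37 and 3 adjusted over the list alone (median 0.28, camera adjusted p = 0.0115, and adjusted p = 0.882 with an estimated correlation), and was not called without starved glucose A (0.0702) or starved xylose A (0.134). Replication, cell cycle and histone genes rose in 36 and fell in 19 of 105 cases, or in 39 and 19 adjusted over the list alone (median 0.11, camera adjusted p = 0.0256, and adjusted p = 0.476 with an estimated correlation), and lost the call without starved glucose B (0.0611) or C (0.0617) or starved xylose B (0.0518). Autophagy rose in 1 and fell in 11 of 30 cases, or in 0 and 11 adjusted over the list alone (median -0.18, camera adjusted p = 0.0348, and adjusted p = 0.209 with an estimated correlation), and lost it without starved glucose A (0.0596) or B (0.0611).

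In starvation 2446 genes differed between the sugars by edgeR quasi-likelihood, 1333 higher and 1113 lower on xylose, and 320 by 2-fold or more. A fit of the starved libraries alone called 1613. Higher genes were 54.5% of the calls with TMM scaling but with library size alone 958 were higher and 1706 lower, so the balance of directions depends on scaling; with library size alone the median gene moved to -0.12 from 0.00. Genes without replicate overlap numbered 2576 (chance 10%), with 2218 of them called, and the self-test recovered 74.6, 91.0 and 98.5% of planted 1.5-, 2- and 4-fold changes. Between the phases the sugar difference was shared by 190 genes that were higher on xylose in both and 97 that were lower in both, where 132 and 120 would come from independent calls, and 326 were called in opposite directions (Pearson 0.18, Spearman -0.09 across genes). The shared rises include snf3, xks1, xyl2, PHBOTO_006039, PHBOTO_003675 and PHBOTO_006510.

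The starvation response of 2218 genes differed between the sugars by edgeR quasi-likelihood, and MEL genes rose less on xylose while ribosomal protein genes fell less. Values in this comparison are the log2 change on xylose minus that on glucose. The MEL values were -2.87 ± 0.23 for mac1, -2.10 ± 0.19 for mac2, -1.68 ± 0.48 for emt1 and -0.76 ± 0.16 for mat1, with -0.49 ± 0.28 uncalled for the exporter mmf1 by edgeR quasi-likelihood (adjusted p = 0.179). The mac1 value combined a difference between sugars of 2.08 ± 0.20 in exponential growth with one of -0.79 ± 0.12 in starvation. For mac2 these were 0.67 ± 0.14 and -1.42 ± 0.12. The emt1 call ended without exponential xylose C (edgeR quasi-likelihood adjusted p = 0.0511), and emt1 had 0.171 ± 0.0369 CPM in exponential xylose. The MEL list had 4 lower values of 6 (median -1.22, camera adjusted p = 0.00185, and adjusted p = 0.161 with an estimated correlation). Cytosolic ribosomal proteins were higher in 71 of 79 cases and lower in 0, and in 75 adjusted over the list alone (median 0.73, camera adjusted p = 2.40e-10, and adjusted p = 0.505 with an estimated correlation), with rpl25 at 1.19 ± 0.19. Mitochondrial ribosomal proteins were higher in 29 of 46 cases, or 30 adjusted over the list alone (median 0.53, camera adjusted p = 1.63e-04, and adjusted p = 0.554 with an estimated correlation), with mrpl3 at 0.98 ± 0.17. Ribosome biogenesis genes were higher in 52 of 91 cases, or 54 adjusted over the list alone, with 1 lower in each (mrm2, named after its value was seen; median 0.48, camera adjusted p = 3.76e-05, and adjusted p = 0.572 with an estimated correlation), with the assembly factor tsr2 at 1.13 ± 0.18.

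The lowest values of named genes were those of a urea transporter and of PHBOTO_006524 and loci with numbers close to it. The pentose phosphate list was lower too, and fatty acid synthesis genes went both ways. The ABC transporter ste6_3 stood at -6.35 ± 0.27, the P450 PHBOTO_006516 at -6.25 ± 0.91 and the fatty acid synthase subunit fas2 at -6.04 ± 0.14, and the glycosyltransferase PHBOTO_006524 at -6.38 ± 1.83. The PHBOTO_006524 call rested on 2 counts in each exponential group and ended without exponential xylose A (edgeR quasi-likelihood adjusted p = 0.0777) or C (adjusted p = 0.0801). The urea transporter dur3_2 had -7.60 ± 1.20, the isomerase PHBOTO_006511 -6.28 ± 0.50 and the transaldolase PHBOTO_006510 -5.32 ± 0.23. The carboxylase acc1 had -1.90 ± 0.12 and the malic enzyme mae1 3.36 ± 0.29. Fatty acid synthesis had 2 higher and 4 lower of 10 genes (median -0.38, camera adjusted p = 7.65e-04, and adjusted p = 0.161 with an estimated correlation). The test pointed down, but fas2 had the largest value in size, and mae1 and ole1 (1.42 ± 0.19) were higher. No list test without fas2 is given here. Pentose phosphate genes were higher in 1 and lower in 7 of 11 cases (median -0.76, camera adjusted p = 3.76e-05, and adjusted p = 0.161 with an estimated correlation), with the first oxidative enzyme zwf1 at -0.87 ± 0.12 (to 891 ± 76.6 CPM in starvation on glucose, 803 ± 9.15 CPM on xylose). Between the sugars zwf1 differed by 0.72 ± 0.08 in exponential growth and by -0.15 ± 0.08 in starvation, the latter uncalled. Of the xylose genes xks1 had -1.70 ± 0.23, xr1 -1.07 ± 0.18, xyl2 0.77 ± 0.12 and the sorbitol dehydrogenase sor1 -3.39 ± 0.16. Autophagy was lower in 12 of 30 cases (median -0.23, camera adjusted p = 0.00810, and adjusted p = 0.161 with an estimated correlation).

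Among the highest values were those of mal31, fre2 and yhk8_5, which were lower on xylose in exponential growth. The sugar transporter PHBOTO_004493 was called as well, but it read 0 in starved glucose and 0.0609 ± 0.105 CPM in starved xylose, so no size is given, and its call ended without starved xylose A (edgeR quasi-likelihood adjusted p = 1.00). The maltose permease mal31 had 6.44 ± 0.41, the ferric reductase fre2 5.29 ± 0.64, the antiporter yhk8_5 5.21 ± 0.41 and the beta-xylanase PHBOTO_003675 4.28 ± 1.05. Of stress and chromatin genes the disaggregase hsp104 had 4.75 ± 0.67, the chaperone ssa4 2.79 ± 0.44, the co-chaperone sti1 1.98 ± 0.31 and the histone hta1 1.61 ± 0.13. In carbon metabolism the alternative oxidase PHBOTO_002482 had 4.06 ± 0.26, pck1 3.04 ± 0.28, fbp1 1.58 ± 0.23, the isocitrate dehydrogenase idh1 1.05 ± 0.13 and icl1 0.75 ± 0.16, and the aminotransferase bat1 had 2.31 ± 0.17. Gluconeogenesis and glyoxylate genes were higher in 6 of 8 cases (median 0.68, camera adjusted p = 0.0158, and adjusted p = 0.343 with an estimated correlation). TCA cycle genes were higher in 10 of 17, or 11 adjusted over the list alone (median 0.40, camera adjusted p = 0.00676, and adjusted p = 0.554 with an estimated correlation). These counts include the misfiled leu4 in the gluconeogenesis list and the misfiled leu2 and lys20 in the TCA list.

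The remaining list calls of this comparison were close to the threshold, and libraries that ended them are named with the camera adjusted p found without them. Chaperones were higher in 12 and lower in 3 of 21 cases (median 0.96, camera adjusted p = 0.0351, and adjusted p = 0.493 with an estimated correlation), but not called without exponential xylose A (0.0518), starved glucose B (0.0560) or starved xylose B (0.0528). Amino acid biosynthesis was higher in 22 and lower in 2 of 53 cases (median 0.27, camera adjusted p = 0.0404, and adjusted p = 0.343 with an estimated correlation), but not without exponential xylose A (0.0518), starved glucose B (0.0560), starved xylose A (0.0735) or starved xylose B (0.0528). Plant polysaccharide hydrolases were higher in 15 and lower in 8 of 43 cases, or 16 and 9 adjusted over the list alone (median 0.45, camera adjusted p = 0.0402, and adjusted p = 0.343 with an estimated correlation), but not without starved glucose A (0.0671) or C (0.0524). Cell wall genes were higher in 13 and lower in 4 of 48 cases (median 0.20, camera adjusted p = 0.0476, and adjusted p = 0.221 with an estimated correlation), but not without exponential glucose B (0.0558), exponential xylose A (0.0677) or B (0.0622), starved glucose B (0.0739) or C (0.0719), or starved xylose B (0.0578) or C (0.0601).

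Values above 0 numbered 1262 and those below 956 among these calls, and 541 genes differed by 2-fold or more. With library size alone the share above 0 was 42.6% (937 against 1260) instead of 56.9%, and the median gene stood at -0.09 instead of 0.03. All 147 genes called in opposite directions by the 2 starvation comparisons were called here. Planted differences of 1.5-, 2- and 4-fold were recovered in 50.7, 85.1 and 95.5% of cases, the lowest shares of the 5 comparisons at the first 2 sizes.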

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

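In this part, the shape of the spread with count, the split of the response into rises and falls, its repeat under other scalings, and the random orders of loci were chosen after the result was seen; the thinning, scaling, all-gene response and neighbour tests were written before it.

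The results of this paragraph drew attention for 1 reason, a starvation response that differed between glucose and xylose. By edgeR quasi-likelihood 2218 genes did so. Camera called 13 lists at the preset correlation and 0 with an estimated correlation. Their camera adjusted p at the preset were 2.40e-10 for cytosolic ribosomal proteins, 3.76e-05 for ribosome biogenesis, 3.76e-05 for the pentose phosphate pathway, 1.63e-04 for mitochondrial ribosomal proteins, 7.65e-04 for fatty acid synthesis, 0.00185 for MEL, 0.00676 for the TCA cycle, 0.00810 for autophagy, 0.0158 for gluconeogenesis and glyoxylate, 0.0351 for chaperones, 0.0402 for plant polysaccharide hydrolases, 0.0404 for amino acid biosynthesis and 0.0476 for the cell wall. Among lipid and sugar genes the log2 differences were -2.87 (mac1), -2.10 (mac2), -1.68 (emt1), -0.76 (mat1), -6.04 (fas2), -1.90 (acc1), -6.35 (ste6_3), -6.38 (PHBOTO_006524), -6.25 (PHBOTO_006516), -6.28 (PHBOTO_006511), -5.32 (PHBOTO_006510), -1.70 (xks1), -1.07 (xr1), 0.77 (xyl2), -3.39 (sor1), -0.87 (zwf1), 6.44 (mal31) and 4.28 (PHBOTO_003675). The fit also gave 11.00 for PHBOTO_004493, which is not a measured size because that gene had 0 counts in starved glucose. Among the other genes they were 5.29 (fre2), 5.21 (yhk8_5), -7.60 (dur3_2), 3.36 (mae1), 4.06 (PHBOTO_002482), 1.58 (fbp1), 3.04 (pck1), 0.75 (icl1), 1.05 (idh1), 2.31 (bat1), 4.75 (hsp104), 2.79 (ssa4), 1.98 (sti1), 1.61 (hta1), 1.19 (rpl25), 0.98 (mrpl3) and 1.13 (tsr2).

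MEL and ribosomal protein genes changed less in starvation on xylose than on glucose. None of the scalings tried removed that difference for the ribosomal protein genes. All of them use relative counts, so a difference in total mRNA between the groups was not tested. The test took the median log2 difference of the 79 ribosomal protein genes between starved xylose and starved glucose. It was 0.64 with TMM, 0.61 with RLE, 0.63 with upper-quartile scaling and 0.52, the lowest, with library size alone. The median difference in response was 0.73, 0.71, 0.72 and 0.61 in the same order, and that of the MEL list -1.22, -1.24, -1.23 and -1.34. If xylose cultures had been less far along 1 common response, most genes would have had the smaller change on xylose, and of 1451 genes tested for this, 58.9% did (interval 56.3 to 61.4%), with 69.2% of 671 genes that fell and 50% of 780 genes that rose. The split depends on scaling: with library size alone the shares were 57.1% of all, 52.8% of falls and 61.2% of rises. The share of all genes stayed between 57.1 and 58.9% under every scaling. With TMM, 597 of the 1451 genes had the larger change on xylose. In addition, 147 genes were called in opposite directions in starvation on glucose and on xylose. By the bounds set for this test, the shares did not decide on that account. For the genes they cover, the larger changes and opposite calls argue against 1 common response as the only cause, if each gene moves steadily 1 way. A common response in which genes turn back with time was not tested. For the MEL and ribosomal protein genes, the account of 1 common response is left open.

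Weak genes in starved glucose spread more between replicates than elsewhere. Exponential glucose libraries thinned at random to the same depth had a variance of 1.24 times the mean, against 1.27 times unthinned. Random thinning can only lower an excess over counting error, so this outcome was fixed in advance. By the same property, random loss of reads alone would not raise the ratio. In starved glucose the variance was already 8.65 times the mean at 5 to 10 counts and 14.4 times at 200 to 500, a ratio of 0.602. Differences in transcription between cultures would leave little excess at the lowest counts only if their relative size were the same at every level. That was not tested, so the values do not decide on this cause. Few distinct molecules read many times over would give a ratio that varies little with count. The ratio was not constant, and rose to 20.4 at 1000 to 3000 counts and 133 at 10000 or more. This cause remains open without read-level data.

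The glycosyltransferase PHBOTO_006524 and the fatty acid synthase fas2 lie in a run of 17 loci with consecutive numbers, PHBOTO_006511 to PHBOTO_006527, that all rose on glucose by at least 4-fold. Neighbours here are taken from locus numbers, since no coordinates were at hand and ends of contigs could not be checked. In 1000 random orders of the loci the longest such run was 5, and 0 were as long. Spill-over of reads from 1 strong neighbour was not the source for most, since 15 of 17 members stood above 10% of their higher neighbour. Of the members 15 rose on xylose too, 16 (all but PHBOTO_006511) were lower in starved xylose than in starved glucose, and 15 had an interaction call. The call of PHBOTO_006513 as lower in starved xylose ended with a replicate block by letter.

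Relabelling the libraries gave a check on the counts of calls. Each comparison of 3 with 3 libraries has 10 splits, of which 1 was the real one and the only one to reach the real count in all 4 comparisons; the highest count in another split was 0, 0, 0 and 2, but with 10 splits the share cannot be under 0.05. For the interaction 1 of 100 draws reached 2218 genes; the highest other, 1761, exchanged all sugar labels in 1 phase and so tests the average sugar difference, and the highest of the rest was 816. For shared starvation calls 1 of 100 pairs reached 3996, and the highest other was 0. That 0 was fixed in advance, because other splits of either starvation comparison called 0 genes and so could share none. The pairs therefore add nothing to the splits of the single comparisons.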

How the results depend on the processing

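None of the 774 results of named genes and 145 of lists reversed under any alternative. Named genes here are all those taken by the rule or chosen afterwards, also where the text leaves them out. Other genes were not followed. Of 9445 named-gene results under changed tools, scaling, filters or models, 9208 stayed on their side of the threshold (called or not), 136 lost a call and 101 gained one; of 9286 with 1 library left out, 8936 stayed, 304 lost a call and 46 gained one. For lists the same 3 numbers were 1034, 66 and 60 of 1160, and 1685, 45 and 10 of 1740. Library size alone ended 4 list calls, counts divided by the low-count variance-to-mean ratio 3 and RLE scaling 1. These losses are not marked beside the lists above. Requiring a 2-fold change left 2587 genes for starvation on glucose, 2539 on xylose, 247 for sugar in exponential growth, 320 for sugar in starvation, 541 for the interaction and 2022 shared starvation calls, as a stricter rule must leave fewer. An adjusted p under 0.01 (edgeR quasi-likelihood) left 715, 1622 and 1401 genes for the 2 sugar comparisons and the interaction. Fits of only the compared groups called 2458 genes for sugar in exponential growth, against 1203, and 1613 in starvation, against 2446; a fit of exponential libraries alone does not take in the wider spread of starved libraries, but the cause was not tested. In exponential growth 1937 were called with counts divided by the low-count variance-to-mean ratio and 2597 with quality weights per group, 2 alternatives chosen after seeing the data, as were the mean-count filter of 500 (4944 genes kept) and the lists without misfiled genes; the cause was not tested. Without misfiled genes camera lost 1 list call (the TCA cycle on glucose, adjusted p = 0.324) and gained 4, oxidative phosphorylation on glucose (adjusted p = 0.0229) and in the interaction (adjusted p = 0.0327), and nitrogen source use and the TCA cycle between sugars in exponential growth (adjusted p = 0.0438 each). List calls numbered 59 of 145 with the preset correlation, 7 with estimated correlations and 112 with fry. The fry count is for a shift of a list in 1 direction, without asking whether its genes moved more than other genes.

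Leaving out 1 library gave 4531 to 4759 genes for starvation on glucose, 4544 to 4845 on xylose, 791 (without exponential glucose B) to 1528 (without starved glucose A) for sugar in exponential growth, 2130 to 2752 for sugar in starvation, 1820 to 2552 for the interaction, 3872 to 4109 shared calls and 51 to 59 list calls. With library size alone the median gene stood at -0.12 for starvation on glucose (main -0.02) and at -0.21 on xylose (main 0.00). The labels do not say whether a replicate letter marks 1 culture at both time points. Letter-matched correlations of residuals ran from -0.12 to 0.17, with 2 of 12 pairs over 0.1 and the own letter highest in 4 of 12, so no pairing was used. A replicate block by letter gave 4691, 4696, 1189, 2364 and 2162 genes, 3980 shared calls and 55 list calls. This block ended the camera calls of the proteasome and the TCA cycle on glucose (adjusted p = 0.0544 each), of glycolysis in exponential growth (adjusted p = 0.0542) and of the cell wall in the interaction (adjusted p = 0.0505). It also ended 13 calls of named genes, of which the text counts PHBOTO_006513 as lower in starved xylose (edgeR quasi-likelihood adjusted p = 0.0776 with the block). At this depth 269 loci with at least 1 read had too few counts to be tested. The self-test found 50.7% of 1.5-fold interaction differences, and its recovery was not split by expression level. A pseudocount alternative was not applicable, because raw counts exist.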

Other observations

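In this part, the genes described and the composition of the locus run were chosen after their values were seen.

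Genes of sulfate uptake and reduction named here fell with nitrogen starvation on both sugars; no list covers them and they were not tested as a group. The sulfate permease sul1 changed by -6.24 ± 0.16 on glucose and -7.15 ± 0.17 on xylose. The sulfate adenylyltransferase met3, which activates sulfate, changed by -5.59 ± 0.24 and -5.29 ± 0.24, the next kinase met14 by -2.41 ± 0.10 and -2.77 ± 0.10, the reductase met16 by -5.22 ± 0.11 and -3.55 ± 0.10, and the sulfite reductase subunit met5 by -3.72 ± 0.10 and -3.02 ± 0.10. Of genes annotated for organic sulfur compounds, 2 named here fell: the sulfonate dioxygenase jlp1 (-4.08 ± 0.18 and -5.01 ± 0.19) and the arylsulfatase PHBOTO_006040 (-5.90 ± 0.23 and -6.75 ± 0.22). The sulfonate dioxygenase-like PHBOTO_005702 went the other way and rose by 9.14 ± 0.29 on glucose and 10.81 ± 0.31 on xylose.

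Some genes for metal uptake and proteases also changed on both sugars, again without a test of the groups. The iron permease fth1 changed by -3.27 ± 0.15 on glucose and -4.39 ± 0.16 on xylose and its partner oxidase fet5 by -3.35 ± 0.11 and -4.44 ± 0.12, while PHBOTO_001245, annotated as a negative regulator of iron uptake, rose by 2.46 ± 0.18 and 2.06 ± 0.17. The zinc transporter zrt1 rose by 4.27 ± 0.20 and 4.76 ± 0.20. The extracellular protease PHBOTO_002983 rose by 6.29 ± 0.14 and 6.03 ± 0.13, and the metalloproteases PHBOTO_005859 and PHBOTO_003891 by 5.27 ± 0.15 and 5.87 ± 0.13 on glucose and by 8.45 ± 0.17 and 7.11 ± 0.14 on xylose.

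The run of 17 loci from PHBOTO_006511 to PHBOTO_006527 holds a glycosyltransferase (PHBOTO_006524), P450 enzymes (erg11_3, PHBOTO_006516), an acetyltransferase (PHBOTO_006519), a fatty acid synthase subunit (fas2), an ABC transporter (ste6_3) and a reductase (gre2_2); 6 members are hypothetical proteins. Random orders of loci gave runs of at most 5, so the run in locus-number order did not arise by chance ordering; positions on contigs were not at hand, and what its products make was not tested. The first member, PHBOTO_006511, behaved unlike the rest, with 882 ± 83.7 CPM in exponential xylose, 5.35 ± 3.55 CPM in starved glucose and a change of -3.89 in starvation on xylose. The next runs held 6 loci (PHBOTO_004536 to PHBOTO_004541) and 5 loci, among them the MEL cluster itself (PHBOTO_003088 to PHBOTO_003092). Loci with consecutive numbers in general had correlated starvation changes (0.259 on glucose).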
